A study of Mus musculus with 2 samples.

How the data were processed

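MicroRNA sequencing (microRNA-seq, short reads from RNA inserts under 30 nt, per the labels) was done on total RNA from the hearts of 10-day-old female mice of the strain B6CASTF1/J, the F1 hybrid of C57BL/6J and CAST/EiJ. The labels give 1 group of 2 hearts, numbered as biological replicates 1 and 2, each from its own biosample and each with 1 library. They name no treatment, second tissue or second age, so no comparison between conditions was made, and no p-value across animals was computed.

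Per the file headers, the authors deposited 1 table of microRNA quantifications per library, made from its reads on the mouse assembly mm10 with GENCODE annotation M21. The values are raw read counts per gene as deposited, not normalized. The aligner, the counting program and their versions are not given in the sources used here. Each table held 2202 miRNA gene IDs and 4 category rows (unmapped, multimapping, outside features and ambiguous reads), with 3 count columns: without regard to strand, on the gene strand and on the opposite strand. All 2202 IDs were matched by ID to the M21 annotation, from which symbols, mm10 coordinates, host genes and hairpin sequences were taken. In these tables reads placed at more than 1 position sit in a category row and are not assigned to genes. A miRNA with near-identical copies in the genome is therefore counted only through its uniquely placed reads, and its level is uncertain.

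The gene-strand column was used as the main measure. The category rows were left out of library sizes and are reported as shares of all reads. CPM, which scale each library to the same total, and percent shares were computed over the counts on named genes. Ratios between the libraries used trimmed mean of M values (TMM) factors from edgeR 4.0.16 in R 4.3.3 and a prior count of 0.5, and are given as replicate 2 over replicate 1. A gene was called detected at 10 or more counts in both libraries. Agreement between libraries was described by correlations across genes of log2(CPM + 1), by a chi-square test of the counts and by edgeR's common dispersion with an intercept as its sole term. Correlations across genes treat genes as if independent, which they are not. For each gene with a summed count of 20 or more, an exact two-sided binomial test compared the 2 libraries given their effective sizes, with Benjamini-Hochberg adjustment at 0.05. This test compares these 2 libraries, not conditions. It was tested on simulated counts for the 375 tested genes, 200 of them changed: it recovered 95.5% of 4-fold, 89.4% of 2-fold and 72.1% of 1.5-fold changes and called 4 of 175 unchanged genes. The simulated counts held counting noise only. These rates therefore do not cover gene-specific variation between animals or libraries.

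There were 17 gene lists (173 members, 167 found under the fixed symbols) and 14 gene pairs. These, the rule for named genes and the tests above were set before the data were examined. The named genes were the 20 with the highest mean CPM, up to 4 leading members of each list (any member of lists of 8 or fewer), the genes of the pairs, and the 5 largest ratios in each direction among genes past the test with a summed count of 100 or more. The difference of a list between libraries is the median log2 ratio of its members with a summed count of 20 or more, with its percentile among 10000 random lists matched on mean CPM in 10 bins. Percentiles below 2.5 or above 97.5 were taken as outside the random lists. Random lists ignore that members of a family or cluster share sequence or a transcript. Computation also used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

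Replicate 1 held 10782737 reads, 4260561 of them on named genes, and replicate 2 held 10201509 and 4583025. A count of 0 allows up to 3 counts, which is 0.704 CPM in replicate 1 and 0.655 CPM in replicate 2. Shares of single libraries carry exact 95% Clopper-Pearson intervals. Intervals and floors cover counting error only, since no molecular identifiers are described. The alternatives were the unstranded column, DESeq2 1.42.0 size factors, total counts, all reads as the denominator, other count minimums and pseudocounts, leaving out the most abundant gene and leaving out each replicate. The signal tracks listed in the file headers were not used here.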

Results

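MicroRNA-seq profiled the miRNA genes of 2 hearts from 10-day-old female B6CASTF1/J mice. The design implies no contrast, so the measurements describe the miRNA content of the tissue and how far the 2 hearts (n = 2, replicates 1 and 2) differed. Reads assigned to named miRNA genes numbered 4260561 in replicate 1 (39.5% of its reads) and 4583025 in replicate 2 (44.9%). Reads placed at more than 1 position took 38.9% and 38.0% of the reads, unmapped reads 16.9% and 12.2%, and reads outside features 4.71% and 4.89%. Of 2202 miRNA genes, 346 had 10 or more counts in both hearts and 1434 had 0 in both.

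Levels and ranks cover uniquely placed reads only, while 38.9% and 38.0% of the reads were placed at more than 1 position. A miRNA with near-identical copies could therefore rank higher than its counts show. By these counts Mir378a was the most abundant gene, at 152441 ± 2742 CPM (SD, n = 2). It lies in an intron of Ppargc1b, a transcriptional coactivator of mitochondrial metabolism, on chromosome 18 (61397835 to 61397900, minus strand, mm10). Its share was 15.4% in replicate 1 (exact 95% interval 15.40 to 15.47) and 15.1% in replicate 2 (15.02 to 15.08). Mir126a, which lies within Egfl7 and is known from endothelium, followed at 112091 ± 36443 CPM on chromosome 2 (26591357 to 26591429, plus strand). It overlaps an exon of an annotated Egfl7 transcript, which need not be the main transcript. The let-7 genes Mirlet7i (88800 ± 10853 CPM, intergenic on chromosome 10, 122985640 to 122985724) and Mirlet7g (57357 ± 7585 CPM, in an intron of Wdr82 on chromosome 9, 106178840 to 106178927) came next. Mir143, a miRNA of smooth muscle, reached 42774 ± 12489 CPM (intergenic on chromosome 18, 61649196 to 61649258).

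The next 5 genes were Mir23b (40902 ± 7853 CPM), Mir99a (38576 ± 9103), Mirlet7b (37897 ± 3136), Mir23a (29996 ± 6063) and Mir30d (28526 ± 2529). Ranks 11 to 20 were held by Mirlet7d, Mir139, Mir26b, Mir99b, Mir22, Mir322, Mirlet7e, Mir30a, Mir125a and Mir652, from 24985 ± 14625 CPM for Mirlet7d to 10760 ± 86.1 CPM for Mir652. The 10 leading genes took 62.9% ± 0.698 of the counts, the 20 leading genes 78.5% ± 1.79 and the 100 leading genes 98.0% ± 0.0172. Of each library's own 20 leading genes, 18 were shared. Mir378a and Mir126a overlap miRNA genes on the opposite strand, and without strand their reads are ambiguous: the CPM of Mir378a is then 0.

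**Figure D1:**
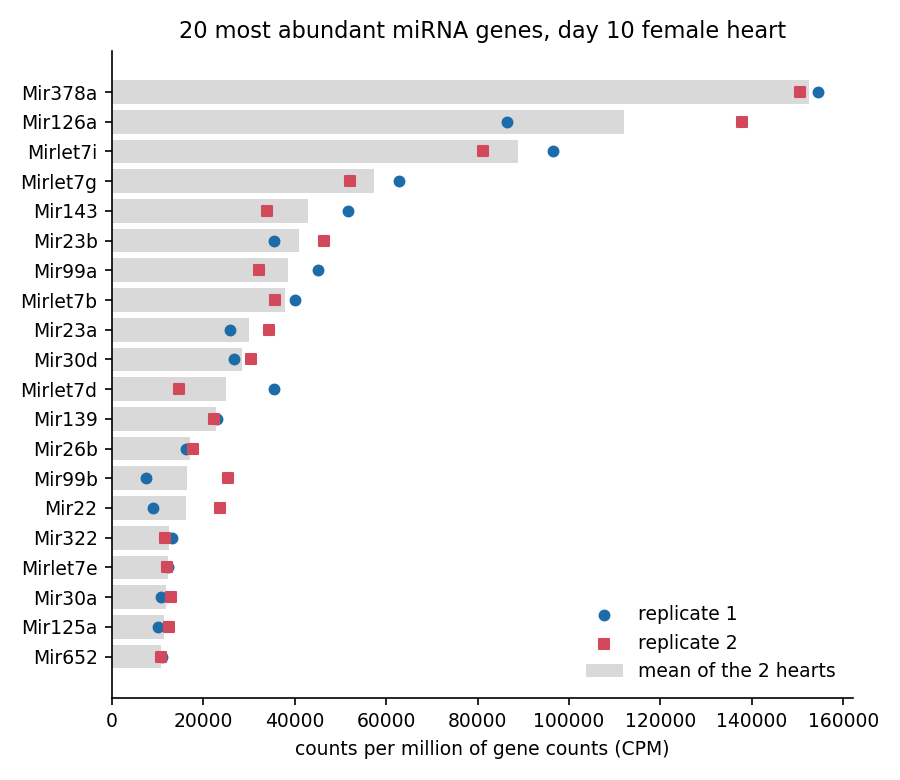
CPM of the 20 most abundant miRNA genes by uniquely placed reads in the hearts (horizontal axis, CPM over gene counts), with bars for the mean of the 2 hearts, circles for replicate 1 and squares for replicate 2. Mir378a lies at 152441 CPM with the hearts close together, while Mir126a, Mirlet7d, Mir99b and Mir22 lie further apart.

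Among the striated and cardiac muscle genes, Mir499, in an intron of the myosin gene Myh7b, led at 4784 ± 931 CPM. Mir208a, in an intron of Myh6 (the alpha myosin heavy chain), stood at 2162 ± 1125 CPM, and Mir208b, in an intron of Myh7 (the beta chain), at 1144 ± 143 CPM. Mir208a exceeded Mir208b by 2.38-fold in replicate 1 (log2 ratio 1.25, exact 95% interval 1.20 to 1.29) and 1.31-fold in replicate 2 (0.39, 0.34 to 0.44). Mir499 exceeded Mir208b by 4.37-fold and 3.96-fold. The whole list of 8 took 0.815% ± 0.220 of the counts, with 6 members detected. The muscle miRNAs Mir1a-1 (2.60 ± 0.026 CPM), Mir1a-2 (48.4 ± 7.10), Mir133a-1 (5.18 ± 3.63) and Mir133a-2 (1.14 ± 0.379) were counted at low levels. These genes share runs of 28 or 31 nt with another miRNA gene, so multimapping reads leave their levels, and the list's share, uncertain. Mir1a-2 exceeded Mir1a-1 16.1-fold and 19.6-fold, Mir133a-1 exceeded Mir133a-2 5.15-fold and 2.78-fold (the log2 interval in replicate 2 was -0.14 to 3.67), and Mir499 exceeded Mir208a 1.84-fold and 3.02-fold.

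Vessel genes took a large part of the counts from uniquely placed reads. The endothelial list took 11.3% ± 3.60, nearly all of it from Mir126a, with Mir221 at 868 ± 395 CPM and Mir222 at 87.6 ± 60.0 CPM; Mir221 exceeded Mir222 8.82-fold and 13.0-fold. Smooth muscle and mural genes took 4.48% ± 1.26, and Mir143 exceeded its cluster mate Mir145a (2069 ± 85.8 CPM) 24.2-fold in replicate 1 and 16.9-fold in replicate 2. Fibroblast and mesenchymal genes took 1.45% ± 0.585, with Mir21a at 8862 ± 6526 CPM, Mir214 at 4881 ± 378, Mir29a at 658 ± 280 and Mir199b, whose copies share 28 nt, at 56.3 ± 10.9. Of the 9 genes of this list, 6 share a run of 22 nt or more with another miRNA gene, so its share is uncertain. Mir29a exceeded Mir29c 11.0-fold and 14.8-fold, but Mir29c shares a 22 nt run with Mir29b-1, so this ratio is uncertain. Mir199a-1 (chromosome 9) had 8 counts and 1 count, or 1.05 ± 1.17 CPM, against 4881 CPM for Mir214 (chromosome 1). The log2 ratio of Mir199a-1 over Mir214 was -11.18 (interval -12.47 to -10.28) in replicate 1 and -13.94 (-19.83 to -12.05) in replicate 2. Mir199a-1 shares a 28 nt run with Mir199b, while Mir214 has no such run, so multimapping reads leave this ratio uncertain. Ratios of different sequences also hold differences in ligation and mapping.

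White blood cell genes took 0.366% ± 0.00789 of the counts, with a median of 154 CPM over the list's 7 members, led by Mir155 (1494 ± 125 CPM), Mir146 (1292 ± 27.3) and Mir150 (622 ± 39.8), with Mir142 at 154 ± 19.6 and the myeloid Mir223 at 100.1 ± 2.83. Erythroid genes took 0.0799% ± 0.0352, with a median of 290.0 CPM over 3 members, against a median of 26.8 CPM over the 8 cardiac muscle genes, 5 of which have near-identical copies. Mir451a stood at 376 ± 206 CPM, Mir486, which muscle also expresses, at 290.0 ± 12.1 and Mir144 at 133 ± 134. The log2 ratio of Mir144 over Mir451a was -2.58 in replicate 1 and -1.19 in replicate 2.

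The let-7 family, a group of differentiation-associated miRNAs, took 23.1% ± 3.77 of the counts, with all 12 members found in the tables detected and 5 of them among the 20 leading genes. Of its members, 6 share a run of 22 nt or more with another miRNA gene. Their median was 436 CPM, against 31441 CPM for the other 6. Such runs were also held by 2 of 6 miR-30, 2 of 7 miR-15/16 and 4 of 15 miR-17 members. Multimapping reads therefore leave the shares of these 4 families uncertain. The log2 ratio of Mirlet7b over Mirlet7g was -0.64 and -0.54. The miR-30 family took 4.99% ± 0.585, led by Mir30d, with Mir30a at 11812 ± 1594 CPM and Mir30e at 8509 ± 1814. The miR-15/16 family took 2.42% ± 0.548, with Mir322 at 12426 ± 1089 CPM and Mir195a at 4475 ± 4315; Mir322 exceeded Mir195a 9.27-fold in replicate 1 and 1.55-fold in replicate 2. The X-linked Mir322 cluster, whose leading gene the miR-15/16 list also holds, took 2.07% ± 0.245, with Mir351 at 6121 ± 1246 CPM, Mir542 at 1491 ± 35.0 and Mir450b at 192 ± 1.26. The miR-17 family clusters took 1.43% ± 0.149, led by Mir93 (5585 ± 648 CPM) and Mir17 (3628 ± 945). Mir17 exceeded Mir92-1 2.30-fold and 1.39-fold, but Mir92-1 shares a 22 nt run with Mir92-2, so this ratio is uncertain. Of the imprinted Dlk1-Dio3 cluster, 44 of 48 genes were detected, taking 1.46% ± 0.264, with Mir127 at 3591 ± 531 CPM, Mir379 at 2515 ± 978, Mir411 at 2110 ± 655 and Mir541 at 1463 ± 50.5.

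By share of counts, which depends on how many genes a list holds, lists of other tissues took 0.0748% or less. Epithelial and pancreatic genes took 0.0748% ± 0.0240 (median 22.9 CPM over 12 members), led by Mir200c at 420 ± 212 CPM, Mir203 at 102 ± 42.3 and Mir215 at 72.5 ± 17.5. Neuronal genes took 0.0271% ± 0.00357 (median 1.82 CPM), led by Mir128-1 at 171 ± 27.2 CPM, and 13 of their 13 members have near-identical copies. The liver gene Mir122 stood at 109 ± 45.7 CPM, a share of 0.0109% ± 0.00457. The skeletal muscle genes Mir206 (17.1 ± 2.64 CPM) and Mir133b (3.36 ± 1.11) took 0.00205% ± 0.000154, and Mir206 exceeded Mir133b 7.09-fold and 3.62-fold. Mir133b shares a 21 nt run with Mir133a-1, so multimapping reads leave its level, this ratio and the list's share uncertain. Of the 12 pluripotency cluster genes 1 was detected, Mir302d, at 5.07 ± 0.858 CPM, and the list took 0.00129% ± 0.000525.

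**Figure D2:**
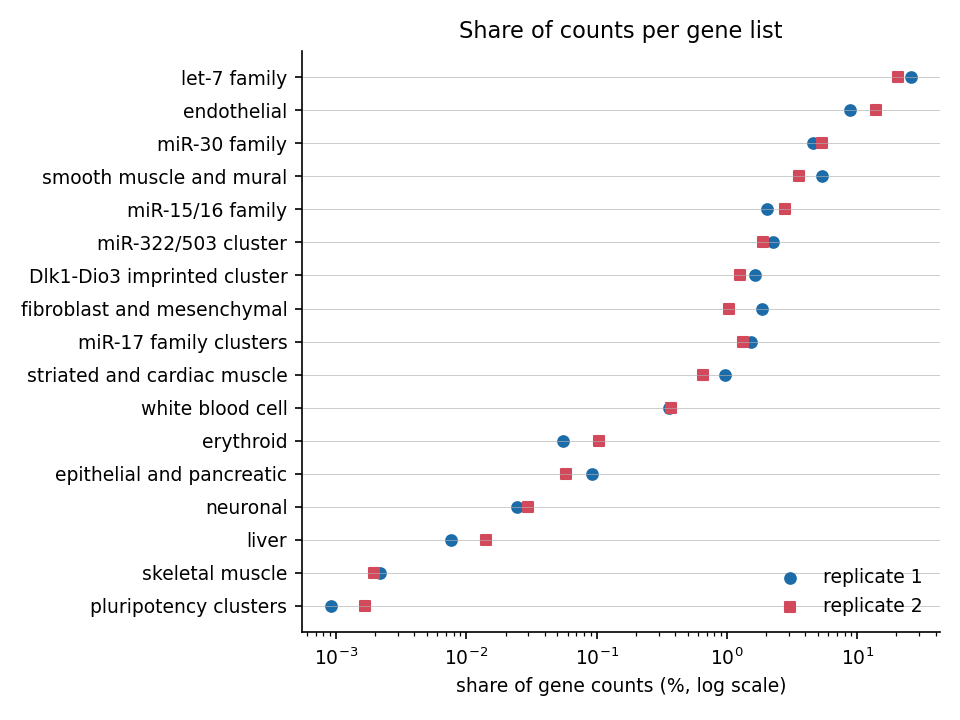
Share of gene counts taken by each gene list (horizontal axis, percent, log scale) in replicate 1 (circles) and replicate 2 (squares). Shares run from 23.1% for the let-7 family to 0.00129% for the pluripotency clusters, as means of the 2 hearts.

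Among genes with a summed count of 100 or more that passed the test between the hearts, Mir301, Mir144, Mir195a, Mir99b and Mir22 had the largest ratios of replicate 2 over replicate 1. Mir301 went from 252 to 3846 counts (log2 ratio 3.89, exact 95% interval 3.71 to 4.08), Mir144 from 163 to 1046 (2.64, 2.40 to 2.89) and Mir195a from 6066 to 34495 (2.47, 2.43 to 2.51). The log2 ratio was 1.83 (1.81 to 1.85) for Mir99b and 1.48 for Mir22. In the other direction, with the same minimum, Mir26a-1 had 668 counts in replicate 1 and 30 in replicate 2 (-4.49, -5.09 to -3.99) and shares a 25 nt run with Mir26a-2. Mir34c (-1.98), Mir669e (-1.73), Mir376c (-1.62) and Mir31 (-1.62) followed, of which Mir669e shares a 24 nt run with Gm27361 and Mir376c a 31 nt run with Mir376b. Of 375 genes tested, 207 differed by more than counting noise (exact binomial test, Benjamini-Hochberg adjusted p under 0.05), 98 higher in replicate 2 and 109 higher in replicate 1, and 40 of the 207 were also 2-fold or more apart. Of 266 genes with a summed count of 100 or more, 241 (90.6%) lay within 2-fold.

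Across all 2202 genes, 1434 of them with 0 counts in both, log2(CPM + 1) of the libraries correlated with Pearson's r 0.992 and Spearman's rho 0.894. Over genes with 10 or more counts in both libraries, r was 0.984 and rho 0.979. The labels give 2 separate biosamples, and the counts of the libraries differed beyond sampling noise (chi-square 301070 on 374 degrees of freedom). edgeR's common dispersion gave a biological coefficient of variation of 0.322.

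**Figure D3:**
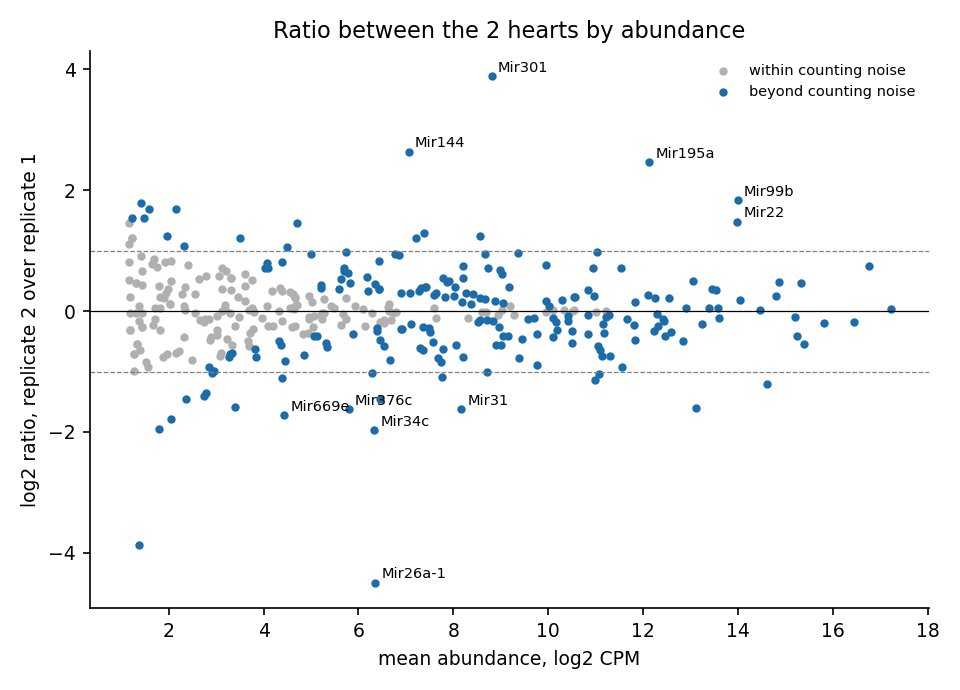
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 375 genes tested, blue where the ratio passed counting noise and grey where not, with dashed lines at 2-fold. Mir301 lies at 3.89 and Mir26a-1 at -4.49.

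Erythroid genes were higher in replicate 2: all 3 passed the test, with a median log2 ratio of 1.25, at the 99.7 percentile of matched random lists. Mir144 (2.64) and Mir451a (1.25), which share a precursor, carried the rise, while Mir486 had a ratio of 0.15 (0.04 to 0.26). Without strand Mir451a and Mir486 have 0 counts, and the list's value of 2.64 (98.5 percentile) is that of Mir144 alone. The miR-15/16 family had a median of 0.71 (99.6 percentile), with 6 members higher in replicate 2 and 1 higher in replicate 1. Epithelial and pancreatic genes had a median of -0.63 (percentile 0.175), with 6 of 12 higher in replicate 1, 3 higher in replicate 2 and 3 not past the test. With a summed count minimum of 200 that median was -0.24 at the 9.97 percentile, inside the random lists. The Dlk1-Dio3 cluster had a median of -0.23 (percentile 0.915), with 15 of 44 higher in replicate 1, 8 higher in replicate 2 and 21 not past the test. The 3 endothelial genes had a median of -0.89 (percentile 1.17), since Mir221 (-0.89) and Mir222 (-1.46) were lower in replicate 2 while Mir126a was higher (0.74), so the list's share and its median differ in sign. Without strand the endothelial median was -0.90 at the 3.32 percentile, inside the random lists. Of the 17 lists, 5 fell outside the random lists and the other 12 inside. Those 12 had medians from -0.28 for smooth muscle and mural genes to 1.05 for the 2 pluripotency genes tested. If members varied independently, about 0.85 lists would fall outside. Members of several lists share a cluster or transcript, so 5 against 0.85 does not measure an excess over chance. The white blood cell list had a median of 0.12 (79.6 percentile) and the let-7 family -0.17 (12.2 percentile).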

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

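The tests of near-identical copies in this part were chosen after list members had been seen at low levels. Reads outside the main measure were looked at because they lie above the 3 counts that a count of 0 allows.

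The largest signal outside the gene counts was the reads placed at more than 1 position, 4193785 in replicate 1 and 3872896 in replicate 2, which are 46.8% and 43.2% of the mapped reads.

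Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 were counted at 1.14 to 48.4 CPM while Mir499 stood at 4784 CPM, and reads shared between paralogs are a candidate explanation. In 6 lists (let-7, miR-15/16, miR-17, miR-30, fibroblast and cardiac muscle), the median log2 CPM of 25 members with a shared run of 22 nt or more differed by -5.70 from that of 32 other members (one-sided stratified permutation p = 0.0001, the smallest that 10000 permutations can give). Without the cardiac muscle list, which prompted the test, the difference was -3.92 (permutation p = 0.0002). Over the 7 lists of both kinds other than cardiac muscle, which add the epithelial and Dlk1-Dio3 lists, it was -0.85 pooled (permutation p = 0.0026) and -5.52 with each member set against its own list (permutation p = 0.0003), and over all 8 it was -1.20 pooled (permutation p = 0.0012). Every version was below 0, but the bound of -2 was not met by both forms over the 7 lists. The pooled form also holds differences in level between lists, which the form set against each member's own list removes. How much of the low counts shared reads explain therefore stays open, and no biological explanation was tested.

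Mir122, Mir203 and Mir5620 had more than 3 reads in both libraries on the strand opposite to the gene, with no annotated miRNA gene there. Mir122 had 19 such reads in replicate 1 and 17 in replicate 2, Mir203 had 12 and 8, and Mir5620 had 5 and 6, against 12 gene-strand counts in each library for Mir5620. Mirlet7b, Mir324, Mir130a, Mir21a and Gm24970 exceeded 3 such reads in 1 library, with at most 8. Over all genes with no opposite miRNA gene, opposite-strand reads numbered 93 in replicate 1 and 69 in replicate 2.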

How the results depend on the processing

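Of 323 values under alternatives, all set before the data were examined, 112 leave out a replicate and 34 rescale list differences. Neither kind says anything of stability: with 2 hearts a mean cannot move by more than 1 SD, and a scaling shifts all genes of a library alike. Of the other 177, 113 were kept, 62 moved, 2 lost their call, and no called value changed sign. The 177 still hold CPM values under TMM and DESeq2 factors, and pair ratios without strand for genes with no opposite-strand partner. Such values could hardly move, so the number kept overstates stability. Kept means within 1 SD of the replicates for levels, within 1.5 times for counts of genes, within 5% for agreement values and on the same side of the threshold for list differences. No paired analysis was possible because there is 1 group. Genes at 1 or more counts numbered 602, against 346 at the minimum of 10. Without strand, the leading 10 genes took 58.5%, the CPM of Mir378a was 0, and list shares in percent were: cardiac muscle 1.14, skeletal muscle 0.00291, smooth muscle 6.33, endothelial 0.135, fibroblast 2.05, erythroid 0.0194, white blood cell 0.4997, neuronal 0.0359, liver 0.0162, epithelial 0.106, let-7 30.9, miR-15/16 3.32, miR-17 2.03, miR-30 5.91, Dlk1-Dio3 1.94 and Mir322 cluster 2.94. Genes with an opposite-strand partner lose most or all of their reads here: Mir126a fell to 9.33 CPM and Mir451a to 0. Without Mir378a the shares were skeletal muscle 0.00242, white blood cell 0.432, neuronal 0.0320, let-7 27.2, miR-17 1.69, miR-30 5.89 and Mir322 cluster 2.45. Over all reads, the CPM of Mir378a was 64306. Spearman's rho was 0.979 over genes with 10 or more counts in both libraries. Genes beyond counting noise that were also 2-fold apart numbered 40, against 207. The endothelial difference was -0.90 without strand (percentile 3.32), and the cause was not tested. The epithelial difference was -0.24 at a summed count of 200 or more (percentile 9.97), and the cause was not tested. Depth limits genes near 0.704 CPM.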

Other observations

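The gene groups of the next paragraph and the tests of shared precursor transcription, paralogs and blood were chosen after the results were seen. The GC test and the library preparation entry were written before their results.

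Intronic miRNA genes took 47.0% ± 0.599 of the counts, genes overlapping an exon of any annotated host transcript 28.7% ± 2.46 and intergenic genes 24.3% ± 1.86 (SD, n = 2). Mir126a within Egfl7, at 11.2% ± 3.64, falls in the exon group by this rule. Genes on chromosome X took 4.68% ± 0.501. Of 119 genes within Sfmbt2, 7 were detected and the group took 0.146% ± 0.0256, while over all genes 346 of 2202 were detected. Mir669e of this group shares a 24 nt run with Gm27361, and reads placed at more than 1 position are not assigned to genes. The level of the Sfmbt2 group is therefore uncertain. In the cluster within Spaca6 on chromosome 17, Mir99b had a log2 ratio of 1.83 between the hearts, while its neighbours Mirlet7e (0.05) and Mir125a (0.37) moved less. In the 2 related clusters, Mir99a (-0.42), Mir100 (-0.42) and Mir125b-2 (-0.57) were lower in replicate 2 and Mir125b-1 (0.22) was higher, while Mirlet7c-1 (-0.01) and Mirlet7a-2 (-0.12) did not pass the test. The Mir125b genes share runs of 24 nt, and Mirlet7c-1 and Mirlet7a-2 runs of 23 nt, with other miRNA genes. Multimapping reads therefore leave the ratios of these genes uncertain. Mir296 (0.94) and Mir298 (-1.15), neighbours on chromosome 2, moved in opposite directions.

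For the gene-specific differences between the hearts, GC content was tested over the whole hairpin, not over the sequenced inserts of under 30 nt. The tables argue against a smooth trend with hairpin GC as their cause. Of the 266 genes with a summed count of 100 or more, 25 were 2-fold apart. After a lowess correction, 24 of these 25 stayed so (share 0.96). Near-identical copies were held by a share of 0.2 of those genes (exact 95% interval 0.068 to 0.407), against 0.191 among the others. Shared precursor transcription stays open: the intraclass correlation within 39 clusters was 0.356 (bootstrap interval 0.064 to 0.551; permutation p = 0.0005, the smallest that 2000 draws can give), and the bound set for it, 0.5, lies inside that interval; a looser bound tried once the value was known was dropped. Library preparation cannot be told apart from the animal, with 1 library per heart, and differences between the animals stay untested.

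Mir144 and Mir451a, which share a precursor, were both higher in replicate 2, with log2 ratios of 2.64 and 1.25, and more blood in that heart is a candidate explanation. The third erythroid gene, Mir486, had a ratio of 0.15 (0.04 to 0.26). This is short of the joint rise written for blood, unless expression in muscle held it down, which was not tested. Mir486 also overlaps Mir3107 on the opposite strand. Overlapping genes were left out of the search for shared runs, so loss of reads placed at both genes cannot be excluded. The ratios of Mir144 and Mir451a differed by 1.39, and the first criterion against blood, counting intervals that do not overlap (2.40 to 2.89 and 1.14 to 1.36), was met. It was replaced after that was seen, because those intervals leave out gene-specific variation: 6 of 88 other adjacent mates lay as far apart, and the 95th percentile of their differences was 1.62. By this second criterion blood and gene-specific variation cannot be told apart, and white blood cell genes had a median of 0.12.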
